A study of Homo sapiens with 16 samples.

How the data were processed

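RNA from 16 samples of the human prostate cancer line LNCaP was sequenced in paired ends, with 4 libraries for each of WT vehicle, WT GCN2iB, p53 KO vehicle and p53 KO GCN2iB. In each well 350000 cells were plated and then given vehicle or 5 µM GCN2iB for 48 h. The deposited file holds raw read counts per gene made by the authors, with no normalization, for 62754 genes. The submitters' processing notes name Trim Galore, HISAT2, featureCounts, DESeq2 and the build GRCh38, without versions, and the annotation release and the strand setting are not given in the sources used here. Each of the 16 columns was matched to a sample by its group and replicate, and 0 columns were left without a sample.

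Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Gene identifiers were matched to symbols (42343 of 62754) and to positions in GENCODE release 29 (58261). Total counts per library ranged from 17418072 to 39915685. Genes were kept by the filterByExpr rule of edgeR, which left 18549 genes that held at least 99.906% of the counts of every library. Totals were scaled by TMM. A quasi-likelihood negative binomial model with 1 term per group was fitted over all 16 libraries with robust dispersion. The 6 contrasts were GCN2iB against vehicle in each genotype, p53 KO against WT under each treatment, the difference between both GCN2iB responses (the interaction), and p53 KO with GCN2iB against WT vehicle. All tests were two-sided. The p-values were adjusted by Benjamini-Hochberg over the tested genes of each contrast, with a threshold of 0.05, and a second count took the called genes with at least a 2-fold change. CPM values are those of edgeR on the scaled totals, and a mean ± SD is over 4 libraries.

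Groups, comparisons, tests, the gene lists and the rule for named genes were fixed before the data were examined. The 27 gene lists, written from general knowledge, hold 629 genes, of which 571 were tested. A list needed 5 tested members, so 26 were tested. The list test was fry of limma on voom log counts with the same model, adjusted over the lists of each contrast, in its directional form, which asks whether the members move one way on balance. Camera, which compares a list with the other genes, was run with an estimated and with a preset correlation of 0.01. The named genes are a fixed set in each comparison, CDKN1A, MDM2, EIF2AK4, ATF4 and ASNS among them, the 6 genes with the largest rise and the 6 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between the groups compared (symbols of clones, pseudogenes and readthroughs left out, and this part not applied to the interaction), and up to 4 members of each list that was called or had at least 25% of its members changed, those with the smallest adjusted p. The text gives those of the lists with the largest share first and leaves out genes whose reads are hard to assign. Some named genes are not reported here.

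Alternatives fixed in advance were DESeq2 size factors, library totals as the only scaling, no count filter beyond 1 count, a mean of at least 50 counts, the DESeq2 and limma voom tests, a fit of the compared groups alone, replicate number as a block, the glmTreat test against a 1.5-fold change, thinning to the smallest library, and each library left out in turn. Chosen after the data were seen were the removal of a smooth trend of each library on GC content and transcript length (5 spline degrees of freedom, fitted on 12999 genes with a mean of at least 50 counts, applied to 17678 genes with both values), the omission of the replicate 4 libraries of GCN2iB in both genotypes, and library totals as the scaling of the list tests. Replicate numbers of different groups were checked for pairing by the correlation of residuals. Of 24 same-number pairs of libraries 5 had r above 0.1. These were the number 1 pair of WT vehicle and p53 KO vehicle (0.246), and pairs of number 4. In number 4, p53 KO GCN2iB went with WT vehicle (0.288), p53 KO vehicle (0.256) and WT GCN2iB (0.141). WT vehicle also went with p53 KO vehicle there (0.236). The median r of the 24 pairs was 0.0366 against -0.0107 in other pairs. Residuals sum to 0 within each group, which pushes other pairs the opposite way, so -0.0107 is no independent baseline. Of the 16 libraries 10 correlated best with their own number. Some structure thus appears shared by number, mostly in replicate 4. The labels name no pairing, so the main fit did not treat the numbers as pairs and the block stayed an alternative.

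To place each library between the genotypes, genes called in a fit of the vehicle libraries alone, with at least a 4-fold difference and at least 5 CPM in the higher group, were taken. The share was the median over them of the distance of a library from the mean of its group without it, divided by the distance from that mean to the other genotype under the same treatment, with a 95% interval from 1000 bootstrap draws of genes. For neighbouring genes, windows of 10 Mb with at least 10 tested genes were compared with 2000 random gene groups of each size. The scripts were tested on simulated data made from these counts. With 18251 genes in the step, the test of GCN2iB in WT cells recovered 23.9% of genes changed 1.25-fold, 62.7% changed 1.5-fold and 78.8% changed 2-fold, and the interaction test 8.96%, 44.8% and 75.8%. A simulated mixture of 25% of the other genotype was returned as 24.8%.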

Results

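Transcript levels were measured in LNCaP cells, a human prostate cancer line that expresses the androgen receptor. Wild-type (WT) and p53 knockout (p53 KO) cells were given vehicle or 5 µM GCN2iB for 48 h. GCN2iB inhibits GCN2, the kinase encoded by EIF2AK4, which phosphorylates the translation factor eIF2 when amino acids run short. Each of the 4 groups held 4 libraries of total RNA, 16 in all. Total counts per library ranged from 17418072 to 39915685. In order of replicate they were 19670655, 33913058, 32258029 and 36626031 for WT vehicle and 32809164, 30225481, 32202493 and 39671776 for WT GCN2iB. They were 39915685, 32127167, 37635701 and 35537608 for p53 KO vehicle and 35542396, 31675429, 17418072 and 36073676 for p53 KO GCN2iB. The series asks what the loss of p53 does to transcript levels when GCN2 is inhibited as well, and its title names purine metabolism. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these libraries only, and they do not say whether the p53 KO cells are a clone or a pool. Levels are in CPM, a gene's counts relative to the scaled total of its library, as mean ± SD of 4 libraries (n = 4), and changes are log2 ratios with standard error (SE). The SE was derived from the test, as the size of the log2 ratio divided by the square root of its F statistic. Genes are said to rise or fall only at an adjusted p under 0.05.

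CDKN1A, the cyclin-dependent kinase inhibitor p21 and a direct p53 target (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339), stood at 275 ± 21.1 CPM in WT vehicle and 37.5 ± 3.73 CPM in p53 KO vehicle. Principal component 1 held 34.4% of the variance and parted the genotypes. Component 2 held 16.4% and parted vehicle from GCN2iB. WT GCN2iB replicate 4 lay nearer to the p53 KO libraries than the other WT GCN2iB libraries did, at -18.26 on component 1 against -33.61 to -31.47. Over 9 genes higher in p53 KO vehicle its level covered 24.8% of the distance to the p53 KO GCN2iB mean, and over 21 genes lower there 20.8%. The other 7 GCN2iB libraries covered -11.2% to 0.805% and -15.3% to 0.223% of the distance to the other genotype. Replicate 4 is part of the reference mean of the other WT GCN2iB libraries, so their negative shares partly reflect it. The upper ends of both ranges came from p53 KO GCN2iB libraries.

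**Figure D1:**
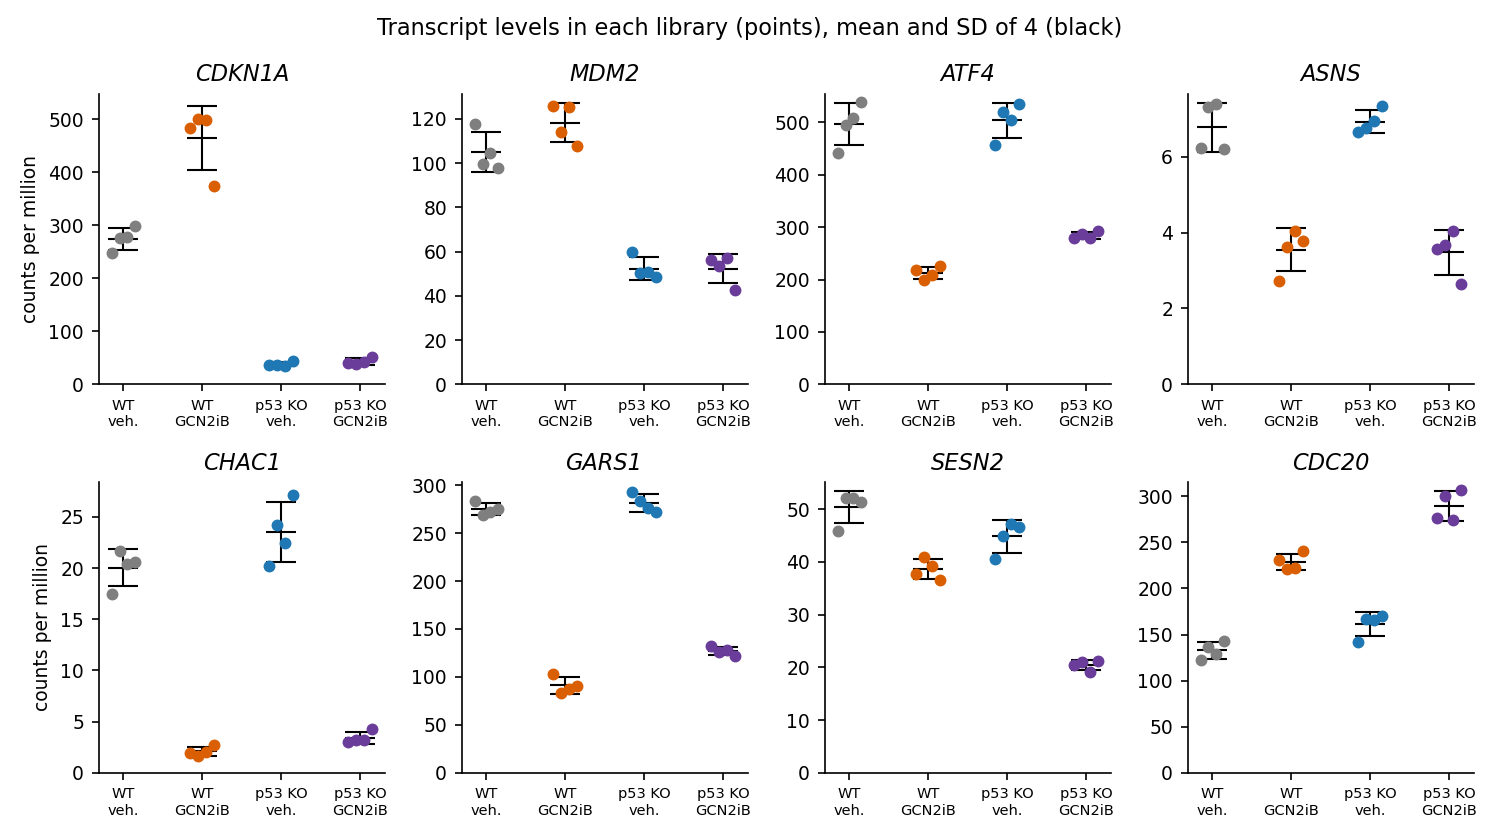
Level of 8 genes in CPM in each of the 16 libraries, by group; each point is a library and the bars give the mean and SD of 4 libraries. CDKN1A averaged 275 CPM in WT vehicle, 464 in WT GCN2iB, 37.5 in p53 KO vehicle and 42.9 in p53 KO GCN2iB.

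**Figure D2:**
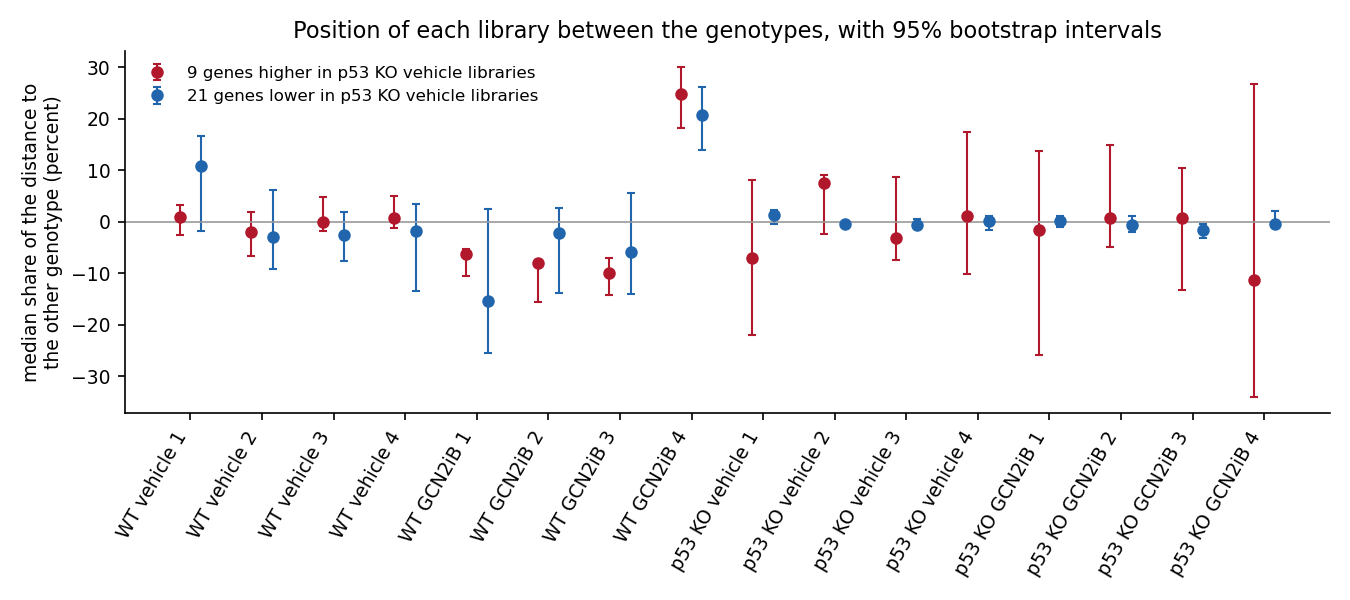
Median share, in percent, of the distance from the library's own genotype to the other genotype, for each library, over genes chosen from the vehicle libraries; bars are 95% bootstrap intervals over genes. WT GCN2iB replicate 4 stands at 24.8% in genes higher in p53 KO and at 20.8% in genes lower in p53 KO.

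Which transcripts change with GCN2iB in cells that have p53 was asked by comparing it with vehicle in WT cells. GCN2iB lowered the transcripts of the amino acid response. The data hold no other inhibitor or dose, so effects of the compound outside GCN2 were not tested. ATF4, the transcription factor whose translation rises when eIF2 is phosphorylated (ENSG00000128272, chromosome 22, 39519695 to 39522685), fell 2.33-fold from 496 ± 40.2 to 213 ± 11.7 CPM (log2 -1.22, SE 0.07, adjusted p = 5.61e-12). CHAC1, a glutathione-degrading enzyme induced by ATF4 (ENSG00000128965, chromosome 15, 40952962 to 40956519), fell 9.53-fold from 20 ± 1.79 to 2.08 ± 0.449 CPM (log2 -3.25, SE 0.14, adjusted p = 7.61e-14). Of 26 tested ATF4 and stress-response genes 22 fell and 0 rose, and 22 also fell when adjusted over the list alone (list adjusted p = 3.67e-10). ADM2, which encodes a secreted peptide, fell 3.31-fold, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 2.28-fold, and STC2, a secreted glycoprotein, 1.65-fold. ASNS, asparagine synthetase, was low at 6.78 ± 0.649 CPM and fell 1.92-fold (adjusted p = 1.29e-05). Of 18 amino acid transporters 11 fell and 1 rose (11 and 2 adjusted over the list alone, list adjusted p = 5.75e-10). SLC7A5, a carrier of large neutral amino acids, fell 4-fold, SLC7A11, of the cystine antiporter, 3.61-fold, SLC6A9, a glycine carrier, 3.5-fold, and SLC1A5, a glutamine carrier, 2.54-fold. Of 20 aminoacyl-tRNA synthetases 13 fell and 2 rose (13 and 2 adjusted over the list alone, list adjusted p = 3.67e-10), with GARS1 3.02-fold, CARS1 2.53-fold and SARS1 1.64-fold lower. Of 24 serine, glycine and one-carbon genes 12 fell and 1 rose (12 and 1 adjusted over the list alone, list adjusted p = 3.67e-10). PSAT1 and PHGDH, enzymes of serine synthesis, fell 1.98-fold and 1.47-fold, and MTHFD2, a mitochondrial folate enzyme, fell 1.65-fold. EIF2AK4 itself fell 1.23-fold (log2 -0.30, adjusted p = 0.00629). BEST1, a chloride channel gene, fell 3.72-fold and was among the 6 largest falls.

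Genes of cell division rose in the same WT cells. Of 32 genes of G2/M and mitosis 25 rose and 0 fell (26 and 0 adjusted over the list alone, list adjusted p = 1.59e-07). CDC20, an activator of the anaphase-promoting complex, rose 1.72-fold from 133 ± 8.82 to 229 ± 8.85 CPM, NDC80, a kinetochore protein, 1.76-fold, and CCNA2, cyclin A2, 1.56-fold. Of 38 genes of DNA replication and S phase 22 rose and 0 fell (26 and 0 adjusted over the list alone, list adjusted p = 1.94e-06), among them UHRF1 at 1.61-fold and MCM7, of the replicative helicase, at 1.47-fold. Pyrimidine and deoxynucleotide synthesis had 8 of 19 genes higher and 1 lower (9 and 1 adjusted over the list alone, list adjusted p = 1.82e-05), with TK1, thymidine kinase, at 1.65-fold and RRM2, of ribonucleotide reductase, at 1.37-fold. CDKN2D, an inhibitor of cyclin-dependent kinases, rose 2.27-fold and UBE2S, a ubiquitin-conjugating enzyme of mitosis, 2.2-fold. UBE2S has processed copies elsewhere in the genome, so its value is uncertain, and it varied widely within WT GCN2iB, at 671 ± 132 CPM. PDXP, a pyridoxal phosphatase, had the largest rise among the named genes, 2.36-fold from 7.35 ± 2.79 to 17.8 ± 2.81 CPM. Of 35 p53 target genes 11 rose and 2 fell (12 and 2 adjusted over the list alone, list adjusted p = 0.000995, adjusted p = 0.146 with an estimated correlation). CDKN1A rose 1.69-fold to 464 ± 60.1 CPM (log2 0.76, SE 0.10, adjusted p = 7.61e-06), PHLDA3 1.8-fold and BAX, a promoter of apoptosis, 1.58-fold. MDM2, which encodes the ubiquitin ligase of p53 (ENSG00000135679, chromosome 12, 68808176 to 68850686), stood at 105 ± 9.05 and 118 ± 8.95 CPM (log2 0.17, adjusted p = 0.148, 0.0141 with the replicate block, 0.0375 with only the groups compared, and 0.000127 with GC and length trends removed and 0.0347 without the replicate 4 libraries of GCN2iB in both genotypes, choices made after the data were seen). In WT GCN2iB replicate 4, the library nearer to the p53 KO cells, CDKN1A was 375 CPM against 483 to 501 CPM in the other WT GCN2iB libraries.

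Androgen receptor targets and endoplasmic reticulum (ER) chaperones fell in WT cells given GCN2iB. Of 30 androgen receptor target genes 23 fell and 0 rose (25 and 0 adjusted over the list alone, list adjusted p = 1.34e-09). PMEPA1 and UAP1 both fell 1.45-fold. Of 24 ER chaperone and unfolded protein response genes 16 fell and 0 rose (17 fell and 3 rose adjusted over the list alone, list adjusted p = 1.02e-07), with PDIA3 1.56-fold, HSP90B1 1.55-fold and HERPUD1 1.52-fold lower. Ribosome biogenesis and MYC targets had 9 of 28 genes higher and 2 lower (list adjusted p = 2.19e-05, adjusted p = 0.0604 with an estimated correlation), with NOP56 and NCL both 1.27-fold higher. De novo purine synthesis had 1 of 13 genes higher and 1 lower (list adjusted p = 0.83, and 0.00351 and up with GC and length trends removed, a choice made after the data were seen), and purine salvage and breakdown 2 of 19 higher and 2 lower (list adjusted p = 0.445). Cholesterol synthesis and uptake had 3 of 23 genes higher and 10 lower (list adjusted p = 0.00094, adjusted p = 0.223 with an estimated correlation), although CYP51A1, a sterol demethylase, rose 1.86-fold. Fatty acid synthesis had 2 of 18 higher and 9 lower (list adjusted p = 0.00182, adjusted p = 0.251 with an estimated correlation), although FASN, the fatty acid synthase, rose 1.41-fold. The eIF2 kinases and factors had 4 of 16 higher and 7 lower (list adjusted p = 2.19e-05, adjusted p = 0.223 with an estimated correlation), and luminal prostate markers 2 of 15 higher and 8 lower (list adjusted p = 2.19e-05, adjusted p = 0.0914 with an estimated correlation). Replication-dependent histones had 6 of 20 higher and 2 lower (list adjusted p = 0.0235, adjusted p = 0.293 with an estimated correlation), and their near-identical copies make them uncertain. Autophagy and lysosome genes had 2 of 30 higher and 9 lower (list adjusted p = 0.00718, adjusted p = 0.376 with an estimated correlation), and the call ended without WT vehicle replicate 3 or 4 (0.0629 and 0.0908) or WT GCN2iB replicate 2 or 3 (0.0701 and 0.0803). Neuroendocrine and basal epithelial markers each had 1 changed gene (list adjusted p = 0.0471 for both, adjusted p = 0.376 and 0.679 with an estimated correlation), and leaving out 1 library ended the calls for 3 and 7 of the 8 libraries, at up to 0.0934 and 0.204. The neuroendocrine call also ended with library totals (0.0577), GC and length trends removed (0.0539) and the replicate 4 libraries of GCN2iB left out (0.0654), and the basal call with DESeq2 size factors (0.0822). The basal list had a median of 0.01 against a mean of -0.01 and a test pointing down. No shift on balance was found for glycolysis and hypoxia genes (list adjusted p = 0.669), interferon-stimulated genes (0.828), NRF2 targets (0.334, and down with library totals at 0.0486 and with GC and length trends removed at 0.0124), mesenchymal and stromal markers (0.0549, and down with the replicate block at 0.012, library totals at 0.0156 and without WT GCN2iB replicate 1 at 0.0322) or mitochondrially encoded mRNAs (0.669). The interferon list had a median of -0.01 and a mean of 0.03, and without the replicate 4 libraries of GCN2iB it fell on balance (list adjusted p = 0.0344). Of 18 immune and blood cell markers 4 passed the count filter, too few for the list test, and 0 of these changed.

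The test of GCN2iB in WT cells called 4677 of 18549 genes, 2153 higher and 2524 lower, of which 113 rose and 111 fell at least 2-fold. The share of calls that were higher was 46%, 38.9% with library totals (1880 higher and 2959 lower), 50.6% with DESeq2 size factors (2341 and 2283), 51.8% with a mean of at least 50 counts (2357 and 2197) and 52.7% with only the groups compared (2561 and 2295). The list test asks whether members move one way on balance and does not compare them with other genes; 9 of the 19 lists it called also held with an estimated correlation between genes, which does.

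**Figure D3:**
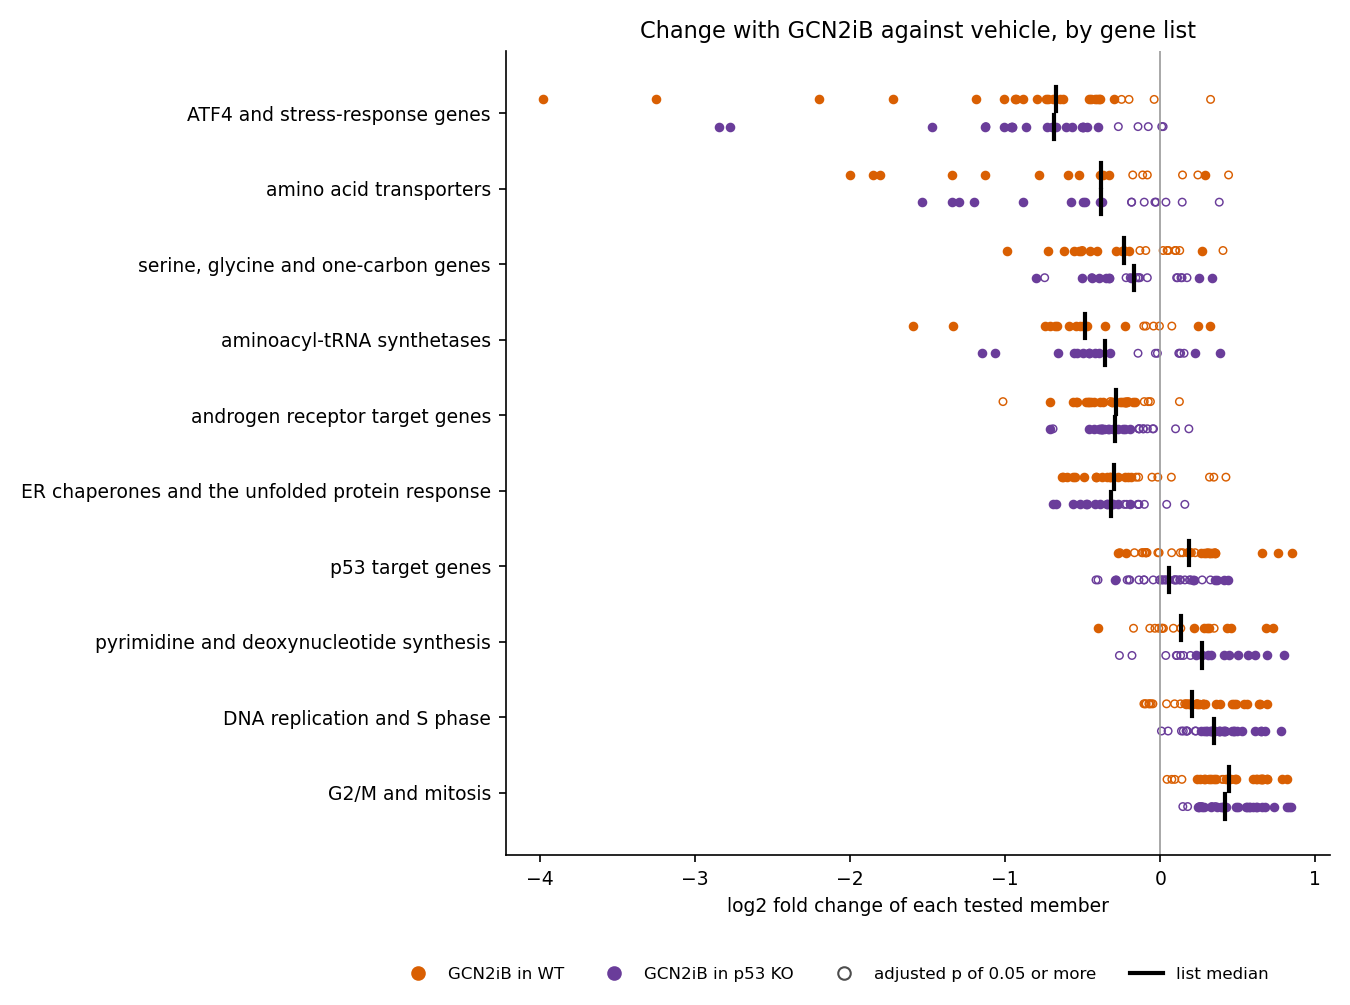
Log2 fold change under GCN2iB against vehicle for each tested member of 10 gene lists, in WT and in p53 KO cells; each point is a gene. ATF4 and stress-response genes lie mostly under 0 in both genotypes, with 22 and 20 of 26 called lower, and genes of G2/M and mitosis above 0, with 25 and 26 of 32 called higher.

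The same comparison in p53 KO cells asked which transcripts change with GCN2iB when p53 is lost. The amino acid response fell in these cells too. ATF4 fell 1.77-fold from 504 ± 33.5 to 284 ± 6.1 CPM (log2 -0.83, SE 0.06, adjusted p = 6.28e-09) and CHAC1 6.85-fold from 23.5 ± 2.93 to 3.4 ± 0.592 CPM (log2 -2.78, SE 0.13, adjusted p = 1.06e-12). Of 26 ATF4 and stress-response genes 20 fell and 0 rose (21 and 0 adjusted over the list alone, list adjusted p = 9.09e-10), with ADM2 2.78-fold, ASNS 2.01-fold and STC2 1.94-fold lower. SESN2, a stress-inducible inhibitor of mTORC1 signalling and a target of both ATF4 and p53 (ENSG00000130766, chromosome 1, 28259527 to 28282491), fell 2.19-fold from 44.8 ± 3.07 to 20.4 ± 0.978 CPM (log2 -1.13, SE 0.07, adjusted p = 1.32e-10). Of 18 amino acid transporters 10 fell and 0 rose, the same counts adjusted over the list alone (list adjusted p = 5.6e-09), among them SLC6A9 at 2.9-fold, SLC7A5 at 2.54-fold, SLC7A11 at 2.46-fold and SLC1A5 at 2.3-fold lower. Of 20 aminoacyl-tRNA synthetases 11 fell and 2 rose (11 and 4 adjusted over the list alone, list adjusted p = 1.25e-08), with GARS1 2.22-fold and CARS1 2.1-fold lower. Of 24 serine, glycine and one-carbon genes 8 fell and 2 rose (9 and 3 adjusted over the list alone, list adjusted p = 1.25e-08), with PSAT1 1.74-fold and MTHFD2 1.42-fold lower. STYXL2, a phosphatase-like gene at 10 ± 0.636 CPM under vehicle, fell 3.31-fold. EIF2AK4 stood at 129 ± 6.99 and 117 ± 14.8 CPM (log2 -0.15, adjusted p = 0.198, and 0.048 with replicate number as a block).

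Cell division genes rose in the p53 KO cells as well. Of 38 genes of DNA replication and S phase 29 rose and 0 fell (36 and 0 adjusted over the list alone, list adjusted p = 1.25e-08), with UHRF1 at 1.71-fold and MCM7 at 1.6-fold. Of 32 genes of G2/M and mitosis 26 rose and 0 fell (28 and 0 adjusted over the list alone, list adjusted p = 5.75e-08), with CDC20 at 1.8-fold, NDC80 at 1.77-fold and CCNA2 at 1.66-fold. Pyrimidine and deoxynucleotide synthesis had 11 of 19 genes higher and 0 lower (14 and 2 adjusted over the list alone, list adjusted p = 3.81e-08), with TK1 at 1.74-fold and RRM2 at 1.53-fold. Ribosome biogenesis and MYC targets had 12 of 28 genes higher and 0 lower (13 and 0 adjusted over the list alone, list adjusted p = 1.25e-08), with NOP56 at 1.44-fold and NCL at 1.34-fold. Of 13 genes of de novo purine synthesis 5 rose and 0 fell, the same counts adjusted over the list alone (list adjusted p = 1e-05, adjusted p = 0.0736 with an estimated correlation and 0.0916 with library totals as the scaling). PFAS rose 1.33-fold from 72.2 ± 4.57 to 96.2 ± 4.58 CPM (log2 0.41, adjusted p = 5.09e-05). In WT cells it rose as well, from 70.4 ± 3.58 to 105 ± 4.33 CPM (log2 0.58, adjusted p = 5e-07), and the difference between the responses did not pass (log2 -0.17, adjusted p = 0.568). PAICS rose 1.18-fold from 493 ± 29.5 to 580 ± 18.7 CPM (adjusted p = 0.0062, and 0.0557 with library totals). CBLN2, a secreted synaptic protein, rose 2.25-fold, KITLG, the ligand of the receptor KIT, 2.21-fold and CDKN2D 2.02-fold. Of 30 androgen receptor targets 19 fell and 0 rose (21 and 0 adjusted over the list alone, list adjusted p = 1.17e-08), with PMEPA1 1.37-fold and UAP1 1.3-fold lower. Of 24 ER chaperone and unfolded protein response genes 16 fell and 0 rose (20 and 0 adjusted over the list alone, list adjusted p = 1.25e-08), with HERPUD1 1.61-fold, HSP90B1 1.43-fold and HSPA5, the chaperone BiP, 1.34-fold lower. Of 35 p53 targets 6 rose and 1 fell (list adjusted p = 0.148, and 0.0357 without the replicate 4 libraries of GCN2iB), and the list pointed down, without a call, under library totals. CDKN1A stood at 37.5 ± 3.73 and 42.9 ± 5.97 CPM (adjusted p = 0.183) and MDM2 at 52.3 ± 5.12 and 52.3 ± 6.59 CPM (adjusted p = 0.985).

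Glycolysis and hypoxia genes had 8 of 27 members higher and 2 lower in p53 KO cells under GCN2iB (list adjusted p = 0.0199, adjusted p = 0.368 with an estimated correlation), with ENO1 1.29-fold and GAPDH 1.22-fold higher. Both genes have processed copies elsewhere in the genome. This call ended under library totals (0.204), without the replicate 4 libraries of GCN2iB (0.0745) and without p53 KO vehicle replicate 2 or 3 (0.0513 and 0.0548) or p53 KO GCN2iB replicate 1 or 4 (0.0576 and 0.0676). Fatty acid synthesis had 0 of 18 genes higher and 6 lower (list adjusted p = 0.000514, adjusted p = 0.125 with an estimated correlation), and cholesterol synthesis and uptake 3 of 23 higher and 6 lower (list adjusted p = 0.00798, adjusted p = 0.316 with an estimated correlation). Basal epithelial markers had 1 of 11 genes lower (list adjusted p = 0.00904, adjusted p = 0.296 with an estimated correlation). Neuroendocrine markers had 1 of 5 higher (list adjusted p = 0.0143, adjusted p = 0.368 with an estimated correlation), and replication-dependent histones 3 of 20 higher (list adjusted p = 0.0313, adjusted p = 0.368 with an estimated correlation). Both calls ended under library totals, at 0.0552 and 0.0805, and that of the histones also with GC and length trends removed (0.123) and without p53 KO vehicle replicate 3 or 4 (0.0738 and 0.055) or p53 KO GCN2iB replicate 1 or 4 (0.0529 and 0.116). No shift on balance was found for purine salvage and breakdown (0.138, and 0.0178 and up with replicate number as a block), interferon-stimulated genes (0.323, and 0.0245 and up without the replicate 4 libraries of GCN2iB), NRF2 targets (0.56), mitochondrially encoded mRNAs (0.151), the eIF2 kinases and factors (0.206), autophagy and lysosome genes (0.148), luminal markers (0.289) or mesenchymal and stromal markers (0.289). The last 5 of these lists, from the mitochondrially encoded mRNAs on, pointed down with a call under library totals (0.0413, 0.00185, 0.000333, 0.00346 and 0.0111). The first 3 of these 5 were also called down with GC and length trends removed (0.0089, 0.0053 and 0.0228), autophagy without p53 KO vehicle replicate 1 (0.0327) and mesenchymal markers with the replicate block (0.0439).

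The test of GCN2iB in p53 KO cells called 3734 genes, 2119 higher and 1615 lower, of which 34 rose and 94 fell at least 2-fold. The share of calls that were higher moved with the scaling and the count filter: it was 56.7%, 34.4% with library totals as the scaling (1401 higher and 2672 lower of 4073) and 47.3% with a mean of at least 50 counts (1853 and 2062). Of the 17 lists called, 10 also held with an estimated correlation.

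Whether p53 status changes the response to GCN2iB was tested as the difference between both responses. For most genes the responses pointed the same way. Of 6010 genes changed in either genotype 5567 (92.6%) had the same sign in both, 1323 rose in both (246 would be shared by independent lists) and 1073 fell in both (219.8), while 5 moved in opposite directions with a call in each. Across all 18549 tested genes, which are not independent replicates, Pearson's r between the log2 changes was 0.509 and Spearman's rho 0.573. 1 gene passed the test of the difference, SESN2, named here after its values were seen. This count was unstable, at 38 with DESeq2, 47 with no filter, 61 with the replicate block, 34 without WT GCN2iB replicate 1 and 10 without p53 KO GCN2iB replicate 4. SESN2 fell from 50.4 ± 3.05 to 38.6 ± 1.94 CPM in WT and from 44.8 ± 3.07 to 20.4 ± 0.978 CPM in p53 KO cells, a difference of -0.74 on the log2 scale (adjusted p = 0.00142). The difference was 0.40 for ATF4 (SE 0.09, adjusted p = 0.225), 0.45 for GARS1 (SE 0.09, adjusted p = 0.0674) and -0.56 for CDKN1A (SE 0.14, adjusted p = 0.286). Other settings turned these into calls, DESeq2 for ATF4 (0.0487), GARS1 (0.00192) and CDKN1A (0.0487), the replicate block for ATF4 (0.0119) and GARS1 (0.00304), no filter for GARS1 (0.0246) and CDKN1A (0.000191), and the absence of p53 KO GCN2iB replicate 4 for GARS1 (0.0334) and CDKN1A (0.0329). GARS1 also passed without WT GCN2iB replicate 1 (0.0108). With GC and length trends removed ATF4 (0.00328) and GARS1 (0.0267) passed, and CDKN1A without the replicate 4 libraries of GCN2iB (0.00115). The differences for MDM2 (-0.18, adjusted p = 0.686), EIF2AK4 (0.16, 0.694) and ASNS (-0.07, 0.939) did not pass.

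In lists, the difference (p53 KO response minus WT response) was positive on balance for 8 of 26. These were serine, glycine and one-carbon genes, aminoacyl-tRNA synthetases, de novo purine synthesis and ribosome biogenesis (list adjusted p = 0.000974 for each), luminal markers (0.00795), and pyrimidine synthesis, DNA replication and S phase, and the eIF2 kinases and factors (0.0103 for each). The median difference was 0.07 for serine and one-carbon genes, 0.13 for the synthetases, 0.13 for de novo purine synthesis and 0.12 for S phase. All 8 calls ended with an estimated correlation (adjusted p = 0.0767 to 0.0869) and all 8 ended with library totals as the scaling, a choice made after the data were seen (adjusted p = 0.139 to 0.416). With DESeq2 size factors, the replicate block, GC and length trends removed or the replicate 4 libraries of GCN2iB left out all 8 stayed called, and with the preset correlation 7 did. Leaving out 1 library ended the call of luminal markers for WT vehicle replicate 4 (0.0594), WT GCN2iB replicate 2 (0.0558) and WT GCN2iB replicate 3 (0.0515). It ended those of pyrimidine synthesis, S phase and the eIF2 factors for 8, 10 and 5 of the 16 libraries, at up to 0.0905, 0.0855 and 0.0759. The p53 target list had a median difference of -0.10 (list adjusted p = 0.23), and without WT GCN2iB replicate 4 it passed in the negative direction (0.00354). The interferon-stimulated genes stood at 0.595 and passed in the positive direction without the same library (0.0223), and amino acid transporters at 0.0689 and passed without p53 KO GCN2iB replicate 4 (0.0362). The ATF4 and stress-response list, which holds SESN2, stood at 0.737, and the G2/M list at 0.737, glycolysis at 0.0689, androgen receptor targets at 0.167 and ER chaperones at 0.318. The remaining lists stood at 0.37 or above. With the replicate block transporters (0.0406) and glycolysis (0.0222) were called up, and with GC and length trends removed transporters (0.0234) and glycolysis (0.0441) up and ER chaperones down (0.0234).

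The genotypes were then compared under vehicle, p53 KO against WT. With 1 p53 KO line, effects of p53 loss cannot be told apart from other differences between the lines. The p53 targets fell. Of 35 tested p53 target genes 30 fell and 0 rose (31 and 0 adjusted over the list alone, list adjusted p = 4.68e-11). CDKN1A was 7.33-fold lower (log2 -2.87, SE 0.10, adjusted p = 1.23e-14) and PHLDA3, an inhibitor of AKT (ENSG00000174307, chromosome 1, 201464383 to 201469237), 20.1-fold lower, at 3.95 ± 0.585 against 79.3 ± 11.4 CPM (log2 -4.33, SE 0.18, adjusted p = 1.25e-11). SPATA18, of mitochondrial quality control, was 13.4-fold, SESN1 3.4-fold, DDB2, of DNA repair, 2.94-fold and MDM2 2-fold lower (adjusted p = 1.14e-08). GDF15, a secreted stress protein that is a target of p53 and of ATF4, fell 2.5-fold from 849 ± 163 to 339 ± 33.6 CPM. SLC22A3, an organic cation transporter (ENSG00000146477, chromosome 6, 160348268 to 160452581), fell 30.7-fold from 13.3 ± 0.617 to 0.435 ± 0.105 CPM (log2 -4.94, SE 0.16, adjusted p = 7.62e-16). MEST, an imprinted gene, was 20.3-fold, SMO, the Hedgehog pathway receptor, 16-fold and GUCY1B1, of soluble guanylate cyclase, 15-fold lower. KRT16, an epithelial keratin (ENSG00000186832, chromosome 17, 41609778 to 41615899), rose 17.1-fold from 0.415 ± 0.229 to 6.71 ± 0.712 CPM (log2 4.10, SE 0.42, adjusted p = 2.45e-06). IGFBP3, which binds insulin-like growth factors, rose 6.27-fold, CCL5, a chemokine, 5.88-fold, EPHA3, an ephrin receptor, 5.04-fold, BASP1 4.93-fold and AGR2, an ER protein of secretory epithelia, 4.58-fold. KRT16 shares sequence with related keratins and was read as uncertain.

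Interferon-stimulated genes and ER chaperones were higher in p53 KO cells under vehicle, and glycolysis genes lower. Of 28 interferon-stimulated genes 18 rose and 1 fell (20 and 1 adjusted over the list alone, list adjusted p = 1.04e-07), with RSAD2 3.96-fold, OAS2 3.48-fold and OASL 2.79-fold higher. Of 24 ER chaperone and unfolded protein response genes 16 rose and 0 fell, the same counts adjusted over the list alone (list adjusted p = 4.52e-08). PDIA4 was 1.6-fold, HERPUD1 1.52-fold and HSPA5 1.52-fold higher. Of 27 glycolysis and hypoxia genes 23 fell and 1 rose, the same counts adjusted over the list alone (list adjusted p = 3.24e-06), with SLC16A3, a lactate exporter, 1.96-fold, PFKFB4 1.86-fold and PFKP 1.44-fold lower. Of 15 luminal prostate markers 6 fell and 1 rose, the same counts adjusted over the list alone (list adjusted p = 1.14e-06). ACP3, prostatic acid phosphatase, was 1.64-fold, EPCAM 1.48-fold and HOXB13 1.29-fold lower, while MSMB, a secreted prostate protein, was 2.59-fold higher. Androgen receptor targets went both ways, with 11 of 30 higher and 7 lower (14 and 7 adjusted over the list alone, list adjusted p = 0.00497, adjusted p = 0.281 with an estimated correlation). KLK2 was 1.58-fold higher, and CAMKK2 and TMPRSS2 were 1.58-fold and 1.43-fold lower. Of 13 mitochondrially encoded mRNAs 11 rose and 0 fell (13 and 0 adjusted over the list alone, list adjusted p = 0.00152, adjusted p = 0.209 with an estimated correlation), with MT-ND1 at 1.42-fold and MT-ND4 at 1.41-fold. MYC was 1.52-fold lower. Basal markers had 5 of 11 higher and 2 lower (list adjusted p = 0.00233, adjusted p = 0.348 with an estimated correlation), with KRT6A, whose reads are shared with related keratins, 7.82-fold higher. Mesenchymal and stromal markers had 5 of 15 higher and 2 lower (list adjusted p = 0.000332, adjusted p = 0.281 with an estimated correlation), and neuroendocrine markers 2 of 5 higher and 1 lower (list adjusted p = 0.0071, adjusted p = 0.348 with an estimated correlation). Of the 4 tested immune and blood cell markers 2 rose.

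ATF4 (log2 0.02, adjusted p = 0.853), ASNS (0.03, 0.912) and EIF2AK4 (-0.09, 0.434) did not pass the test between genotypes under vehicle. ATF4 and stress-response genes had 7 of 26 higher and 3 lower (list adjusted p = 0.0164), and G2/M and mitosis 10 of 32 higher and 1 lower (0.0386), with adjusted p = 0.348 with an estimated correlation for both. Leaving out 1 library ended these calls for 4 and 6 of the 8 libraries, at up to 0.0858 and 0.135. Purine salvage and breakdown had 6 of 19 lower and 1 higher (list adjusted p = 0.00258, adjusted p = 0.348 with an estimated correlation). A further 7 lists pointed down by small amounts, and their calls ended with library totals as the scaling. They were serine and one-carbon genes (0.000357, then 0.849), ribosome biogenesis (0.00208, then 0.963), the eIF2 factors (0.00218, then 0.658), S phase (0.00258, then 0.164), pyrimidine synthesis (0.0071, then 0.594), fatty acid synthesis (0.0454, then 0.892) and the tRNA synthetases (0.0386, then 0.873 and pointing up). None of these 7 held with an estimated correlation (adjusted p = 0.281 to 0.521), and leaving out 1 library ended the calls of fatty acid synthesis and the tRNA synthetases for 7 and 5 of the 8 libraries, at up to 0.136 and 0.0855. These 2 also ended with DESeq2 size factors (0.0744 and 0.0607), and the synthetases with GC and length trends removed (0.0567). De novo purine synthesis (0.102, a median of 0.01 and a mean of -0.01), amino acid transporters (0.102), cholesterol synthesis (0.36), NRF2 targets (0.167), autophagy and lysosome genes (0.218, a median of -0.01 and a mean of 0.07) and histones (0.0789) did not pass. Under library totals the last 5 of these, from the transporters on, were called up (0.0145, 0.00247, 0.0098, 0.00203 and 0.0148), and with GC and length trends removed as well (0.00155, 0.022, 0.00903, 0.00753 and 0.0147). With the replicate block transporters (0.0231), NRF2 targets (0.016) and histones (0.0437) were called up too, and histones without the replicate 4 libraries of GCN2iB (0.0158). The test called 4025 genes, 1787 higher and 2238 lower, of which 408 rose and 344 fell at least 2-fold; 44.4% were higher, 60.8% with library totals as the scaling (2467 higher and 1593 lower of 4060) and 51.5% with a mean of at least 50 counts (1700 and 1602). Of 20 lists called, 5 also held with an estimated correlation.

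In some regions of the chromosomes neighbouring genes differed between the genotypes in the same direction. Of 299 windows of 10 Mb with at least 10 tested genes, 43 had a median log2 difference under vehicle outside the 99% range of random gene groups. For independent neighbours 2.99 would be expected, but each GCN2iB comparison, made within a genotype, had 16. The 43 windows held 862 (22.1%) of the 3897 called genes with a position and 2584 (14.6%) of the 17641 tested genes with a position. They were picked for a shift in this same comparison, so a larger share of its called genes is built in. The window at 10000001 to 20000000 of chromosome 14 had a median of 0.84 over 12 genes and that at 70000001 to 80000000 of chromosome 5 a median of -0.29. The window at 30000001 to 40000000 of chromosome 6, which holds CDKN1A, had a median of -0.21 over 194 genes.

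**Figure D4:**
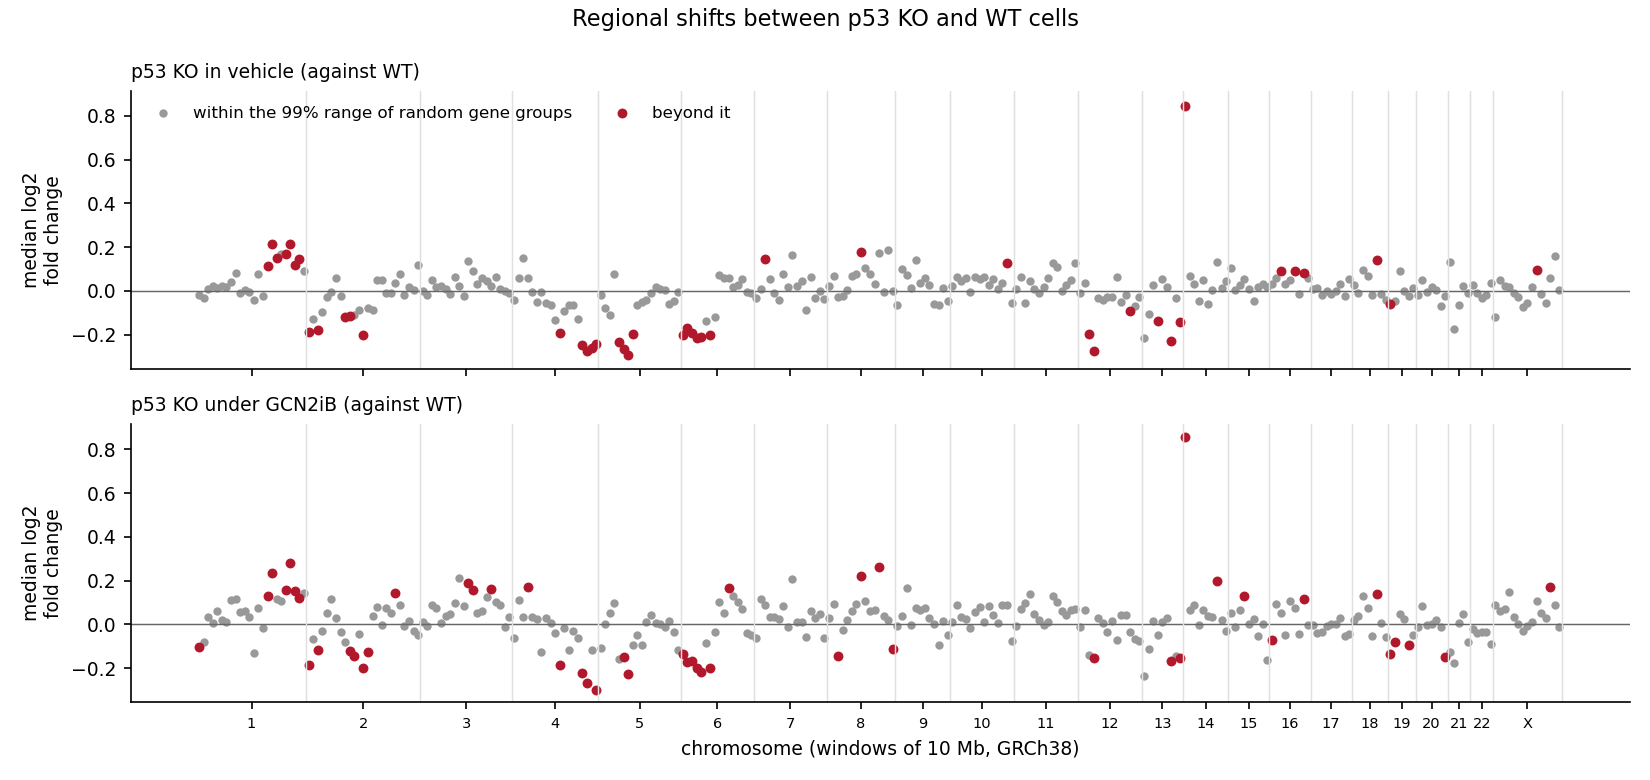
Median log2 fold change of p53 KO against WT in each 10 Mb window along the chromosomes, under vehicle and under GCN2iB; each point is a window, and marked points lie outside the 99% range of random gene groups. Of the 43 windows beyond that range under vehicle, 43 shifted the same way under GCN2iB.

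The same genotype comparison was made under GCN2iB, with the same limit of 1 p53 KO line. p53 targets were again lower. Of 35, 30 fell and 1 rose (33 and 1 adjusted over the list alone, list adjusted p = 1.88e-11). CDKN1A was 10.8-fold lower, at 42.9 ± 5.97 against 464 ± 60.1 CPM (log2 -3.43, SE 0.11, adjusted p = 1.9e-15). PHLDA3 was 30.1-fold, SPATA18 10.2-fold, BTG2, an antiproliferative gene, 3.09-fold, DDB2 2.89-fold, MDM2 2.27-fold and SESN2 1.88-fold lower. MEST was 24.3-fold, SLC22A3 19.4-fold, SMO 16.4-fold and CEL, a lipase, 11.9-fold lower. KRT16 was 8.77-fold, CCL5 4.64-fold, IGFBP3 4.59-fold and EPHA3 4.18-fold higher. Of 28 interferon-stimulated genes 21 rose and 2 fell, the same counts adjusted over the list alone (list adjusted p = 6.14e-08). CXCL10, a chemokine, was 4.45-fold, IFIT1 4.08-fold, IFIT3 3.87-fold and OASL 3-fold higher. WT GCN2iB replicate 4 stood apart toward the p53 KO cells in several of these genes, with KRT16 at 1.79 CPM against 0.289 to 0.466, IGFBP3 at 30.1 against 12.6 to 14.5, IFIT3 at 20.4 against 9.88 to 11.2 and OASL at 64 against 39.4 to 43.1 CPM in the other WT GCN2iB libraries. Of 24 ER chaperone and unfolded protein response genes 18 rose and 0 fell (19 and 0 adjusted over the list alone, list adjusted p = 2.2e-07), with PDIA4 1.52-fold, HSP90B1 1.45-fold and HSPA5 1.37-fold higher.

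**Figure D5:**
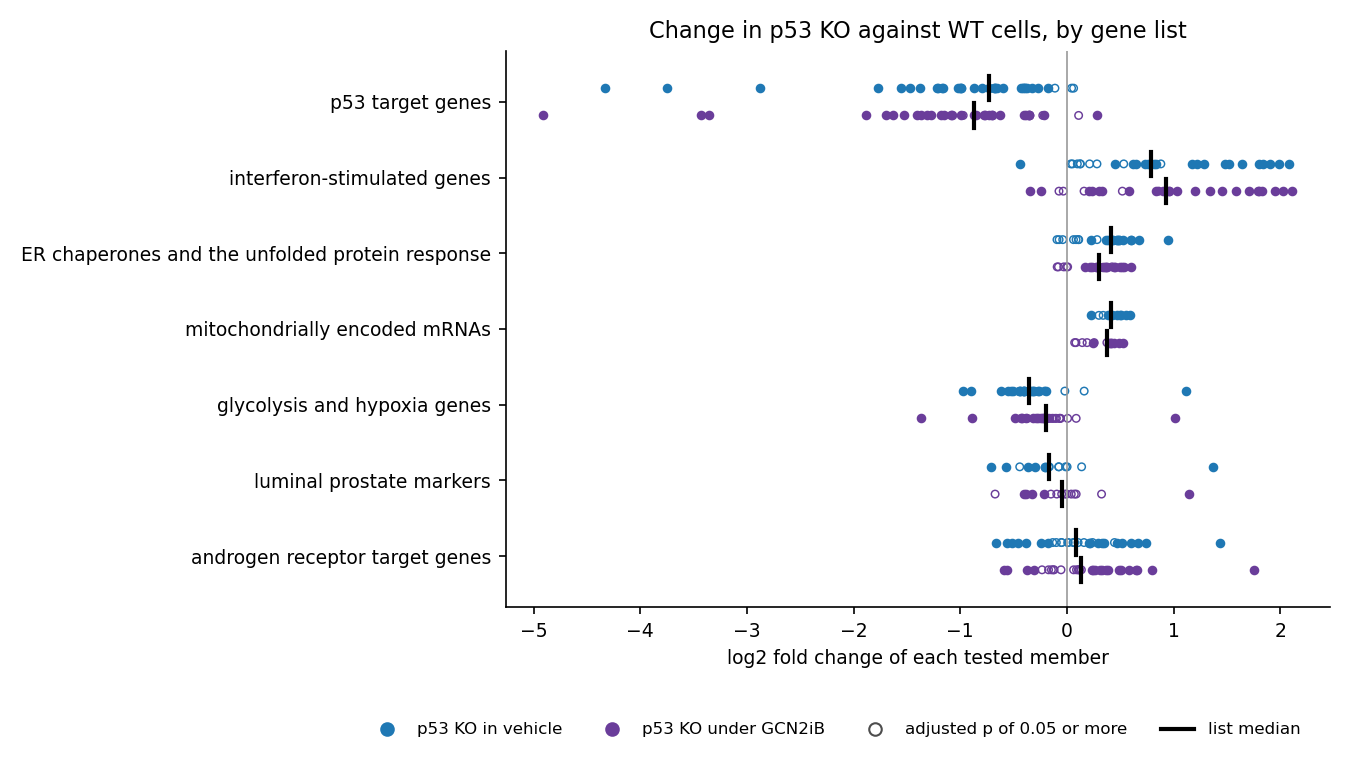
Log2 fold change of p53 KO against WT for each tested member of 7 gene lists, under vehicle and under GCN2iB; each point is a gene. Of 35 p53 target genes 30 were called lower under each treatment, and of 28 interferon-stimulated genes 18 and 21 were called higher.

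Several transcripts of the amino acid response were higher in p53 KO than in WT cells when both were given GCN2iB. ATF4 was 1.34-fold higher (log2 0.42, adjusted p = 3.99e-05), SLC7A5 1.85-fold, SLC7A11 1.66-fold, ADM2 1.61-fold, CARS1 1.4-fold and GARS1 1.39-fold higher. Of 26 ATF4 and stress-response genes 11 rose and 4 fell (13 and 4 adjusted over the list alone, list adjusted p = 0.0142, adjusted p = 0.399 with an estimated correlation). That call ended with DESeq2 size factors (0.0576), without the replicate 4 libraries of GCN2iB (0.155) and without 7 of the 8 libraries in turn, at up to 0.212. Amino acid transporters had 7 of 18 higher and 4 lower, and aminoacyl-tRNA synthetases 6 of 20 higher and 2 lower (list adjusted p = 0.00109 for both, adjusted p = 0.399 with an estimated correlation for both). De novo purine synthesis had 1 of 13 higher and 0 lower (list adjusted p = 0.000386, adjusted p = 0.388 with an estimated correlation), and PFAS stood at 105 ± 4.33 CPM in WT and 96.2 ± 4.58 CPM in p53 KO cells (adjusted p = 0.123). Glycolysis and hypoxia genes had 13 of 27 lower and 1 higher (15 and 1 adjusted over the list alone, list adjusted p = 0.000386, adjusted p = 0.231 with an estimated correlation), with SLC16A3 2.58-fold lower. Androgen receptor targets had 14 of 30 higher and 4 lower (list adjusted p = 0.000151, adjusted p = 0.231 with an estimated correlation), with KLK2 1.5-fold higher. Mitochondrially encoded mRNAs had 7 of 13 higher (list adjusted p = 0.00881, adjusted p = 0.397 with an estimated correlation), with MT-ND1 at 1.31-fold. Fatty acid synthesis had 7 of 18 lower and 4 higher (list adjusted p = 0.0104, adjusted p = 0.399 with an estimated correlation, 0.0872 with library totals), with FASN 1.31-fold lower.

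Mesenchymal markers had 4 of 15 genes higher and 3 lower under GCN2iB (list adjusted p = 0.000115), neuroendocrine markers 2 of 5 higher and 1 lower (0.00473), luminal markers 4 of 15 lower and 1 higher (0.00482), purine salvage 5 of 19 lower and 3 higher (0.0125) and NRF2 targets 6 of 20 higher and 2 lower (0.0104). With an estimated correlation none of these 5 held (adjusted p = 0.294 to 0.456), and the NRF2 call ended without WT GCN2iB replicate 1, 2 or 3 (0.0735, 0.0953 and 0.0637). Basal markers (0.00757, with a median of -0.00 and a mean of 0.20), G2/M and mitosis (0.0104), ribosome biogenesis (0.00881) and autophagy and lysosome genes (0.0104) pointed up and did not hold with an estimated correlation either (adjusted p = 0.399 to 0.494). The basal call ended with the replicate block (0.067) and without WT GCN2iB replicate 2 (0.0508), and those of G2/M, ribosome biogenesis and autophagy without 4, 4 and 6 of the 8 libraries in turn, at up to 0.0662, 0.343 and 0.16. The calls of ribosome biogenesis (0.0954) and autophagy (0.059) also ended with DESeq2 size factors, those of G2/M (0.0528) and ribosome biogenesis (0.0595) with GC and length trends removed, and that of ribosome biogenesis without the replicate 4 libraries of GCN2iB (0.101). Serine and one-carbon genes (0.136, with a median of 0.06 and a mean of -0.00), pyrimidine synthesis (0.124), S phase (0.32), cholesterol synthesis (0.0514), histones (0.124) and the eIF2 factors (0.309) did not pass. Other settings called some of these up, the replicate block serine and one-carbon genes (0.00351), library totals pyrimidine synthesis (0.0184) and cholesterol synthesis (0.00845), and the absence of p53 KO GCN2iB replicate 2 cholesterol synthesis (0.0238) and of WT GCN2iB replicate 4 histones (0.0442). The test called 4441 genes, 2356 higher and 2085 lower, of which 384 rose and 354 fell at least 2-fold; 53.1% were higher, 57.9% with library totals, 48.1% with DESeq2 size factors, 47.8% with a mean of at least 50 counts and 46.3% with only the groups compared. 1416 genes were lower and 1120 higher in p53 KO cells under both treatments, where independent lists would share 251.6 and 227. Of 20 lists called, 3 also held with an estimated correlation.

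The state of p53 KO cells given GCN2iB against untreated WT cells combined both changes. Of 35 p53 targets 30 fell and 1 rose, the same counts adjusted over the list alone (list adjusted p = 1.38e-10), and of 26 ATF4 and stress-response genes 21 fell and 1 rose (21 and 2 adjusted over the list alone, list adjusted p = 1.56e-09). Of 32 genes of G2/M and mitosis 28 rose and 0 fell (30 and 0 adjusted over the list alone, list adjusted p = 1.38e-08), and of 28 interferon-stimulated genes 21 rose and 3 fell, the same counts adjusted over the list alone (list adjusted p = 2.7e-08). ER chaperones, which were higher in p53 KO than in WT cells and lower with GCN2iB, had 7 of 24 genes higher and 5 lower (list adjusted p = 0.892, with a median of -0.05 and a mean of 0.04). De novo purine synthesis had 3 of 13 higher and 1 lower (list adjusted p = 8.78e-05, adjusted p = 0.228 with an estimated correlation). This comparison called 6870 genes, 3436 higher and 3434 lower, of which 499 rose and 486 fell at least 2-fold. Of 21 lists called, 12 also held with an estimated correlation.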

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

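The tests of WT GCN2iB replicate 4 and of the libraries behind the interaction lists were chosen only after the result was seen, as were library totals as the scaling of the list tests, and the removal of GC and length trends was chosen after the data were seen. In 500 groups of 4 values, the highest or lowest library stood apart in 36, where chance would give about 1 in 20, or 25.

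WT GCN2iB replicate 4 lay toward the p53 KO libraries. It stood at -18.26 on principal component 1 against -33.61 to -31.47 in the other WT GCN2iB libraries, at 24.8% (95% interval 18.2 to 30) of the distance to p53 KO GCN2iB over 9 genes higher in p53 KO, and at 20.8% (14 to 26.2) over 21 genes lower. The tables argue against a swapped label, since the upper bound of 30% is under the midpoint, and against sequencing depth, since the share was 26.1% after thinning (highest other 3.16%). Open is that p53 KO cells or their RNA may have been mixed into the sample. Both sets of genes gave like shares, above the -15.3% to 0.805% of the other 7 GCN2iB libraries. The lower end of that range belongs to a WT GCN2iB library whose reference mean includes replicate 4, and so partly reflects it. A simulated 25% mixture of the group means was returned as 24.8% over 29 genes. This checks the calculation only and cannot tell mixing from another cause. Lower p53 activity in that sample stays open too: genes lower in p53 KO and outside the p53 target list gave 20.7% (highest other 0.799%), but they were picked for differing between the genotypes and may depend on p53 without being listed.

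In that library CDKN1A was 374.9 CPM against 482.9 to 501.1 in the other WT GCN2iB libraries. KRT16 was 1.795 CPM against 0.2891 to 0.4656, and KRT6A 1.093 against 0.1606 to 0.2353. IGFBP3 was 30.1 CPM against 12.6 to 14.46, AGR2 38.5 against 15.33 to 19.17, and BASP1 3.746 against 1.766 to 2.084. RSAD2 was 11.79 CPM against 5.804 to 6.681, OASL 64 against 39.38 to 43.15, and IFIT3 20.45 against 9.881 to 11.18. The mean log2 CPM of the interferon-stimulated genes was 3.205 against 2.829 to 2.848.

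Neighbouring genes shifted together between the genotypes. In 43 of 299 windows of 10 Mb the median difference under vehicle was outside the 99% range of random gene groups. This compares with 2.99 expected for independent neighbours and 16 in each GCN2iB comparison. All 43 shifted the same way under GCN2iB, in other libraries, and 30 were again outside the range. This is consistent with a difference in copy number or regional silencing between the WT and the p53 KO line, which these counts cannot separate from genes that are regulated with their neighbours. With 1 p53 KO line, whether such regions follow from p53 loss or from the separate history of the lines was not tested.

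SESN2 differed in its response to GCN2iB by -0.742 on the log2 scale between p53 KO and WT cells. In the opposite direction, 8 gene lists had a positive difference on balance. They included serine, glycine and one-carbon genes, aminoacyl-tRNA synthetases, de novo purine synthesis and ribosome biogenesis (list adjusted p = 0.000974 each) and luminal prostate markers (0.00795). The others were pyrimidine and deoxynucleotide synthesis, DNA replication and S phase, and the eIF2 kinases and factors (0.0103 each). Of the 8 lists 0 held with an estimated correlation (adjusted p = 0.0767 to 0.0869). The tables argue against WT GCN2iB replicate 4 or p53 KO GCN2iB replicate 4 as the source, as 7 lists stayed called without the first and 8 without the second, though 4 of the 8 lost their call without other single libraries, at up to 0.0905. Bias by GC content and transcript length was not the whole source of the calls, since 8 lists stayed called with these trends removed. Their adjusted p was then 0.00871 to 0.0475. It rose for the lists other than the eIF2 kinases and factors. For de novo purine synthesis it went from 0.000974 to 0.0234 and for S phase from 0.0103 to 0.0475, so this bias may account for a part of the shifts. Open is the scaling of the libraries, as 0 of the 8 lists stayed called with library totals (adjusted p = 0.139 to 0.416) although 8 did with DESeq2 size factors. Library totals moved the median difference over all tested genes from 0.023 to -0.017. A change of scaling shifts all genes nearly alike, so the lost calls cannot tell whether the scaling is the source. A response that depends on p53, as the design asks, stays open too.

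p53 KO GCN2iB replicate 4 stood at -30.55 on principal component 2 against -13.87 to -10.92 in its group, and its counts had a log2 slope of -0.141 per doubling of transcript length against -0.025 to -0.006. Its residuals correlated with those of replicate 4 of WT vehicle (r = 0.288), p53 KO vehicle (0.256) and WT GCN2iB (0.141). In p53 KO GCN2iB replicate 4, CHAC1 was 4.28 CPM against 2.987 to 3.17, SLC1A5 70.26 against 58.57 to 60.41, and UBE2S 924.6 against 553.5 to 601.5. TK1 was 426.1 CPM against 358.6 to 367.4, and HOXB13 461.9 against 386.9 to 395.5. WT vehicle replicate 1 stood at 10.8% of the distance to p53 KO vehicle over the 21 genes lower in p53 KO, against -2.96% to -1.75%, with a 95% interval of -1.8 to 16.6 that includes 0, and at 0.945% over the 9 genes higher in p53 KO. It held MCM7 at 387.9 CPM against 447.4 to 454.1 and SESN2 at 45.81 against 51.36 to 52.16. In p53 KO vehicle replicate 1, CDC20 was 141.6 CPM against 166.2 to 170.1, GAPDH 1536 against 1723 to 1759, and OASL 90.7 against 103 to 104.9. In p53 KO vehicle replicate 4, CDKN1A was 43.06 CPM against 35.35 to 36.11 and PMEPA1 187.8 against 165.6 to 168.4. In WT vehicle replicate 4, NOP56 was 283.7 CPM against 270.8 to 270.9, SLC16A3 14.07 against 10.28 to 10.84, and MSMB 2.322 against 1.67 to 1.739. WT vehicle replicate 3 had SLC7A5 at 15.98 CPM against 17.5 to 17.77. WT GCN2iB replicate 1 had CDKN2D at 32.72 CPM against 36.37 to 36.97. WT GCN2iB replicate 2 had a log2 slope of 0.095 per 10 percent of GC against 0.047 to 0.053. p53 KO GCN2iB replicate 2 had IFIT1 at 76.92 CPM against 79.86 to 80.28. p53 KO GCN2iB replicate 3 had PDXP at 7.717 CPM against 9.9 to 10.16, and a mean log2 CPM of the ATF4 and stress-response genes of 4.656 against 4.68 to 4.681.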

How the results depend on the processing

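Chosen only after the data were seen were the removal of GC and length trends, the omission of the replicate 4 libraries of GCN2iB, and library totals as the scaling of the list tests. The counts of GCN2iB in WT and in p53 KO cells, of p53 KO in vehicle and under GCN2iB, and of p53 KO with GCN2iB against WT vehicle stayed within 1.5 times their values under each alternative run except glmTreat. Against a 1.5-fold change glmTreat called 45 genes for GCN2iB in WT and 24 in p53 KO cells (6 higher and 18 lower), 487 for p53 KO in vehicle, 458 under GCN2iB and 714 for both against WT vehicle; its stricter hypothesis shows the cause. With each library left out in turn these counts ranged from 3448 to 4505, 2798 to 3688, 3140 to 4192, 3308 to 4857 and 5890 to 6687, with fewer samples in each fit. Replicate number as a block gave 6139, 5301, 5203, 5775 and 8098 genes. The labels do not say that the numbers pair the samples, though 10 of the 16 libraries correlated best with their own number.

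The count of the interaction was less stable. Against 1 gene it was 2 with DESeq2 size factors, 4 with library totals, 47 with no count filter, 6 with a mean of at least 50 counts, 38 with the DESeq2 test, 61 with the replicate block, 14 with GC and length trends removed and 6 without the replicate 4 libraries of GCN2iB. It was 0 with glmTreat of edgeR, where 166 genes had an unadjusted p under 0.05. Leaving out 1 library gave 1 to 34 genes: 34 without WT GCN2iB replicate 1, 10 without p53 KO GCN2iB replicate 4, 5 without WT GCN2iB replicate 4 and 2 without WT vehicle replicate 3, WT GCN2iB replicate 3 or p53 KO vehicle replicate 4. SESN2 was among the calls in each of these settings except glmTreat, with a log2 difference of -0.81 to -0.71. The cause was not tested for the others. For CDKN1A the adjusted p of the interaction, 0.286, ranged from 0.000191 (no filter) to 1 (glmTreat).

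The correlation of both GCN2iB responses across genes, 0.509, was 0.0565 with no filter, which adds genes with few counts, 0.743 with a mean of at least 50 counts, which leaves them out, 0.554 after thinning and 0.409 without the replicate 4 libraries of GCN2iB. Leaving out 1 library gave 0.414 to 0.485. The cause was not tested for the last 3 values. Of the list calls, 84 over 5 comparisons, 27 were also made by camera with an estimated correlation and 49 with its preset correlation, which made 53 calls in all, 4 of them on lists that fry did not call. Camera compares a list with other genes. Of the 8 interaction lists, S phase lost its call without WT vehicle replicate 2 (0.0855), 3 (0.0802) or 4 (0.0605), WT GCN2iB replicate 2 (0.0603), 3 (0.0832) or 4 (0.0615), p53 KO vehicle replicate 1 (0.0705), 3 (0.0528) or 4 (0.0566), or p53 KO GCN2iB replicate 3 (0.0619). Pyrimidine synthesis lost it without 8 of these libraries, WT GCN2iB replicate 4 and p53 KO vehicle replicate 4 being the exceptions, at up to 0.0905. The eIF2 factors lost it without WT vehicle replicate 3 (0.0759), WT GCN2iB replicate 2 (0.0603), p53 KO vehicle replicate 3 (0.0528) or 4 (0.0602), or p53 KO GCN2iB replicate 3 (0.0507), and luminal markers without WT vehicle replicate 4 (0.0594) or WT GCN2iB replicate 2 (0.0558) or 3 (0.0515). The call of aminoacyl-tRNA synthetases for p53 KO in vehicle turned from down to up without a call under library totals (adjusted p = 0.873). Library totals moved the median log2 change over all tested genes in this comparison from 0.006 to 0.064, the way the list turned. Whether this shift is the whole cause was not tested. Of 14 calls of the fixed genes glmTreat kept 5, and of 373 calls of named genes 99, while no named gene changed direction with a call. MDM2 in WT cells given GCN2iB, not called (0.148), was called with the groups compared alone (0.0375), the replicate block (0.0141), GC and length trends removed (0.000127) and the replicate 4 libraries of GCN2iB left out (0.0347). In data simulated from these counts 62.7% of genes changed 1.5-fold were recovered for GCN2iB in WT cells and 44.8% for the interaction.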

Other observations

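In p53 KO cells given GCN2iB against untreated WT cells, further gene groups moved. Androgen receptor targets had 15 of 30 genes lower and 5 higher (list adjusted p = 1.72e-07), amino acid transporters 11 of 18 lower and 1 higher (1.02e-08), aminoacyl-tRNA synthetases 13 of 20 lower and 1 higher (3.18e-09), and serine, glycine and one-carbon genes 10 of 24 lower and 1 higher (1.56e-09). DNA replication and S phase had 26 of 38 genes higher and 2 lower (4.9e-07), pyrimidine and deoxynucleotide synthesis 10 of 19 higher and 2 lower (1.47e-06), and ribosome biogenesis and MYC targets 12 of 28 higher and 4 lower (6.06e-07). Luminal prostate markers had 8 of 15 lower and 2 higher (1.83e-07). These lists also held with an estimated correlation. Glycolysis and hypoxia genes had 17 of 27 lower and 1 higher (8.36e-05, adjusted p = 0.153 with an estimated correlation), and replication-dependent histones 12 of 20 higher and 0 lower (0.000871, adjusted p = 0.197 with an estimated correlation). Fatty acid synthesis had 10 of 18 lower and 1 higher (1.48e-05, adjusted p = 0.121 with an estimated correlation). The lists of this comparison were not run under the other scalings.

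The trend of counts on GC content and transcript length differed between libraries. It took 28.2% of the variance of the log2 deviation in p53 KO vehicle replicate 1, 26.1% in p53 KO GCN2iB replicate 4 and 22.5% in WT vehicle replicate 1. For the comparisons a separate straight-line fit on GC content and length was used. Across genes that line took 9.33% of the variance of the GCN2iB response in WT cells and 8.41% of that in p53 KO cells. It took 0.472% of the genotype difference under vehicle and 7.23% of the interaction.

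Other splits of the same libraries, tests written before the result was seen, were counted for each comparison. For GCN2iB in WT cells 1 of 35 splits, the real one, gave as many genes (4677, highest other 1), and for GCN2iB in p53 KO cells 1 of 35 (3734, highest other 0). For p53 KO in vehicle it was 1 of 35 (4025, highest other 754), for p53 KO under GCN2iB 1 of 35 (4441, highest other 780) and for p53 KO with GCN2iB against WT vehicle 1 of 35 (6870, highest other 295). In each of these 5 comparisons no other split reached the count of the real one. Every other split mixes libraries of both groups, which widens the spread within groups and tends to lower the number of calls. The labels also do not say whether replicates are separate cultures, so the splits cannot exclude chance. For the interaction, 12 of 100 relabellings gave at least its 1 gene, so chance is not excluded for the count. The highest other gave 3577. It kept the WT labels and exchanged those of 6 of the 8 p53 KO libraries, a structure of the samples that puts the effect of GCN2iB itself into the difference, so these relabellings are no clean measure of chance.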
